A study of Homo sapiens with 6 samples.

How the data were processed

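Poly(A)-selected RNA of Panc-1, a human epithelial cell line from a pancreatic cancer, was sequenced after 72 h of co-culture with cancer-associated fibroblasts (CAF) or with CAF overexpressing PAI-1, per the labels, with 3 biological replicates in each of 2 groups. The labels do not say whether replicates came from separate experiments, so p-values measure the spread between these libraries. They also do not say how Panc-1 and CAF were kept or taken apart before RNA extraction. The extraction text in the labels speaks of another cell line, Cal27, treated with Stattic or DMSO, while title, source, growth and treatment labels all name Panc-1; marker levels that bear on the cell type are therefore given with the results.

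The authors deposited a single table of whole-number counts per gene, with 1 column for each of the 6 libraries, and no other column of sample values was left aside. The columns of the CAF group are headed CAF-NC, and the meaning of NC is not given in the sources used here. The submitters' processing notes name BWA, Bowtie2, RSEM and the build hg19, with no versions or roles. RSEM gives estimated counts that need not be whole, and the deposited counts are all whole, so the step that produced them is not given in the sources used here. The 58735 gene identifiers of the table are exactly those of GENCODE release 29, an annotation of GRCh38, which differs from the hg19 of the processing notes. Coordinates below are those of GENCODE release 29 on GRCh38 and are given to identify genes, not as the positions used in alignment. Of the gene names in the table, 58708 equal those of the annotation and 27 had been turned into calendar dates, and these were restored through the identifier. How reads shared by paralogs, pseudogenes or overlapping genes were assigned, and whether strand was used, is not given in the sources used here. Values of such genes are uncertain for that reason.

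Library totals ranged from 13628508 to 16006880 counts, so that 3 counts in a library correspond to between 0.187 and 0.22 CPM (counts scaled to the library total). Pairs of libraries of a group were compared for duplication over genes with at least 20 reads in the pair. Their chi-square per degree of freedom lay between 2.58 and 9.51, above sampling noise. No library is therefore a copy of another, and each was counted as 1 replicate. This does not show that the cultures were independent. The common biological coefficient of variation, the spread between replicates beyond sampling noise, was 6.06%.

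Genes were tested with edgeR 4.0.16 in R 4.3.3 with filterByExpr (minimum count 10, minimum total 15), TMM scaling, estimateDisp, robust glmQLFit and glmQLFTest, without covariates, as CAF overexpressing PAI-1 minus CAF. Benjamini-Hochberg adjusted p-values under 0.05 over the 14960 genes that passed the filter are called changed, and "rose" and "fell" are used of these alone. All adjusted p-values of single genes are from this test unless another is named. Standard errors are the unshrunken log2 fold change divided by the root of the F statistic. Levels are TMM-scaled CPM with the SD over 3 libraries unless said otherwise. Numbers of markers under 1 CPM use the library total alone.

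There were 38 gene lists, fixed before the data were examined, as were the tests and most alternatives. The 35 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, which takes its degrees of freedom from the libraries and so has less power here, and fry were run beside it. Counts of members are given over all genes tested and adjusted over the list alone. The genes named were set by a rule made at the same time. It takes the 6 genes per direction with the largest fold change among changed genes with a mean of at least 5 CPM and no overlap between groups, and the 2 members with the smallest p of each of the 8 lists with the smallest camera p. It adds the 2 most abundant members of each list of markers of another cell type, of the squamous list and of the pancreatic list, and lets a list's members with the smallest p serve as examples. Some results, with a part of this rule, are not reported here. Members that the rule does not reach are named with their values where they describe a list.

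Alternatives were RLE scaling, library size alone, 3 other filters on low counts, DESeq2 1.42.0, limma-voom, a fit without robust estimation, glmTreat against a 1.2-fold change, the replicate number as a block and each library left out in turn. Leaving out mitochondrial genes and an offset for GC content and transcript length (5 spline terms each) were added after seeing the data. In simulated data with the means and library sizes of this comparison, 92 of 100 genes changed 2-fold and 74 of 100 changed 1.5-fold were recovered among 14811 genes by the edgeR test, with 6 false calls among 172. Of simulated lists, camera called 1 of 1 moved and 0 of 20 unmoved. The genes were simulated independently and with the same spread, so this does not test camera where members of a list are correlated. In the data, the estimated correlation reached 0.52 for cytosolic ribosomal proteins and 0.76 for mitochondrially encoded transcripts. Figures were drawn with matplotlib 3.10.9.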

Results

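Gene expression was measured by RNA sequencing in 6 libraries of Panc-1 cells, a human pancreatic cancer line of epithelial type. In 3 libraries the cells had spent 72 h with cancer-associated fibroblasts (CAF) and in the other 3 with CAF made to overexpress PAI-1, an inhibitor of plasminogen activators. The comparison asks how Panc-1 responds when its fibroblast partner makes more PAI-1. CAF replicates 1, 2 and 3 held 16006880, 15648564 and 13628508 counts, and the replicates with PAI-1 overexpression held 15250915, 13992583 and 15880653. Log2 CPM of libraries of a group correlated across genes at r = 0.990 to 0.992, and of different groups at 0.980 to 0.983, where genes are not independent replicates. The first principal component took up 51.6% of the variance and separated the groups.

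Expression changed widely. Of 14960 genes tested, 4810 (32.2%) changed, 2571 of them higher and 2239 lower with CAF overexpressing PAI-1, and 6178 had an unadjusted p under 0.05. Most changes were small, with a median absolute log2 fold change of 0.39 among changed genes. At least 1.5-fold changes numbered 581 higher and 677 lower, and at least 2-fold changes 199 higher and 246 lower. The groups did not overlap for 6486 genes (43.4%), where chance gives 10%. The balance of directions depends on the scaling, since library size alone gave 1839 higher and 3182 lower. RLE scaling gave 2511 and 2285, close to the main test.

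The 6 largest rises among genes of at least 5 CPM belonged to immediate early transcription factors and regulators of growth factor signalling. EGR2 and EGR1, zinc finger factors induced by growth factors, rose 36.5-fold and 34.8-fold, with log2 fold changes of 5.19 (SE 0.28, edgeR adjusted p = 1.58e-16) and 5.12 (SE 0.071, adjusted p = 3.25e-33). EGR1 went from 16.3 ± 1.26 to 566 ± 27.0 CPM (SD, n = 3 each), while EGR2 went from 0.282 ± 0.036 to 10.5 ± 1.45 CPM, close to the level of 3 counts in the CAF libraries. EGR4 rose by 2.92, FOS by 2.86, SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, by 2.45 and FOSB by 2.35 on the log2 scale (adjusted p from 4.64e-24 to 1.42e-08). EGR1 (ENSG00000120738) lies on the plus strand of chromosome 5, from 138465490 to 138469315 on GRCh38.

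**Figure D1:**
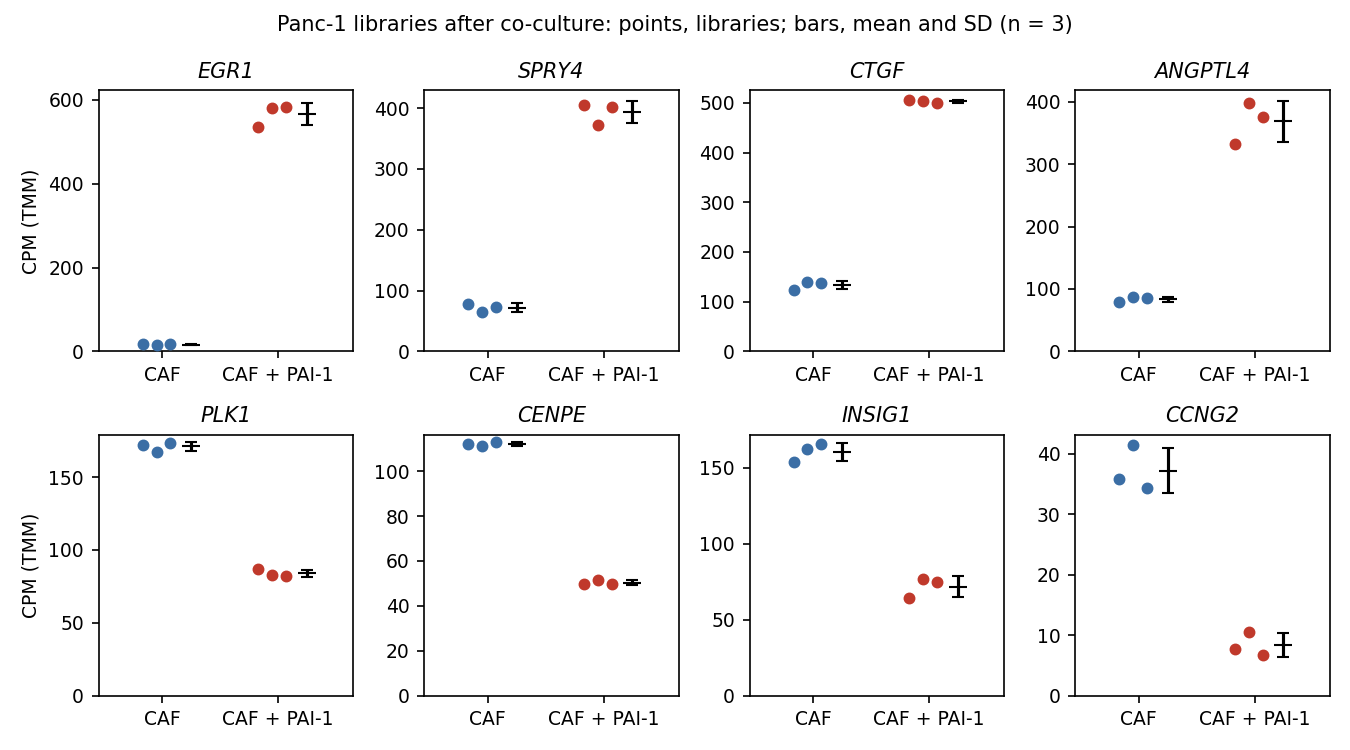
TMM-scaled CPM (vertical axis, from 0) of 8 genes in each library, with points for libraries and bars for the mean and SD of 3 libraries per co-culture. The groups do not overlap for any of the 8 genes, and EGR1 goes from 16.3 to 566 CPM on average.

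The 6 largest falls among genes of at least 5 CPM were of genes with different known roles. BMF, a pro-apoptotic BCL2 family member, had a log2 fold change of -2.45 (SE 0.14, adjusted p = 2.52e-15), going from 24.4 ± 3.09 to 4.45 ± 0.95 CPM. CCNG2, an unconventional cyclin linked to cell cycle arrest, had -2.16 (SE 0.12, adjusted p = 2.79e-15) and went from 37.2 ± 3.71 to 8.35 ± 1.97 CPM. SLC2A12, a sugar transporter, had -2.08, PIF1, a DNA helicase, -1.85, TP53INP1, a p53-inducible gene, -1.78 and KLHL24 -1.66 (adjusted p from 4.95e-18 to 5.58e-12). CCNG2 (ENSG00000138764) lies on the plus strand of chromosome 4, from 77157151 to 77433388 on GRCh38.

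**Figure D2:**
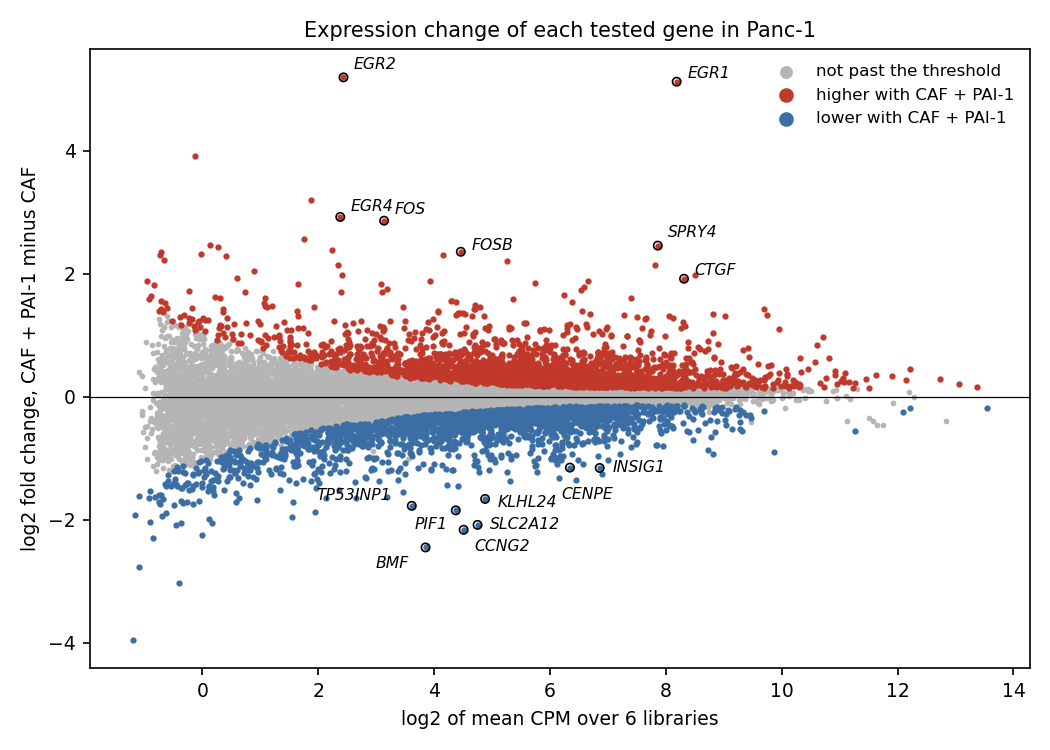
Log2 fold change (vertical axis) against the log2 of the mean CPM over 6 libraries (horizontal axis) for 14960 genes, with 2571 higher genes in red, 2239 lower genes in blue and the others in grey, and named genes ringed. EGR1 and EGR2 stand above all other genes, at 5.12 and 5.19.

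The list of MAPK, AP-1 and immediate early genes moved as a group. Of 34 members tested, 30 rose and 1 fell, SPRY1, and the numbers were the same adjusted over the list alone. The median log2 fold change was 1.36, or 2.56-fold (camera adjusted p = 1.6e-19). This call also holds with an estimated correlation, with an adjusted p = 0.0146, which was true of no other list. JUN rose by 1.98, DUSP5, a phosphatase that acts on ERK, by 1.87, IER2 by 1.78 and JUNB by 1.74 on the log2 scale. ETV4, ETV5 and SPRED2, also in the list, had log2 fold changes of -0.10, -0.09 and -0.01 and did not pass.

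Genes of G2 and mitosis moved the other way. Of 34 members, 32 fell and none rose, also adjusted over the list alone, with a median log2 fold change of -0.79 (0.579-fold, camera adjusted p = 4.72e-21, adjusted p = 0.102 with an estimated correlation). CENPE, a kinetochore motor, went from 112 ± 0.96 to 50.4 ± 1.06 CPM (log2 fold change -1.15, SE 0.063, adjusted p = 4.35e-16), and PLK1, a mitotic kinase, from 171 ± 3.25 to 83.9 ± 2.42 CPM (-1.03, SE 0.058, adjusted p = 7.76e-16). KIF20A had -1.33 and CENPF -0.94, and the members that did not pass were CDC25B at -0.08 and UBE2C at 0.06. In the list for DNA replication and G1/S, 12 of 35 members rose and 4 fell, 13 and 4 adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.0136, adjusted p = 0.364 with an estimated correlation). CCNE1 and CCNE2, the E-type cyclins of S phase entry, rose by 0.98 and 1.22, and CDC6, a replication licensing factor, by 0.52. Replication-dependent histones, whose RNAs mostly lack a poly(A) tail, had 2 members higher and 1 lower of 10 and no call (camera adjusted p = 0.86).

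Genes of the stress response of the endoplasmic reticulum and of ribosome production were higher. In the list of unfolded protein response and ATF4 targets, 32 of 35 members rose and none fell, also adjusted over the list alone (median log2 fold change 0.44, camera adjusted p = 5.15e-14, adjusted p = 0.19 with an estimated correlation). ATF3 rose 2.69-fold, to 37.6 ± 1.87 CPM (log2 fold change 1.43, SE 0.096), TRIB3 from 50.1 ± 3.51 to 100.1 ± 5.47 CPM (1.00, SE 0.068), and XBP1, a transcription factor of the response, rose by 0.91. Of 31 MYC targets and ribosome biogenesis genes, 22 rose and none fell, 23 and 1 adjusted over the list alone (median 0.45, camera adjusted p = 5.21e-11, adjusted p = 0.0975 with an estimated correlation). DDX21, a nucleolar helicase, rose by 0.74 (SE 0.052) and RRP12, a ribosome export factor, by 0.80 (SE 0.058). Heat shock and chaperone genes rose in 13 of 24 members and fell in none, also adjusted over the list alone, led by HSPA8 at 0.97 and DNAJB1 at 0.71 (median 0.20, camera adjusted p = 6.88e-06, adjusted p = 0.255 with an estimated correlation). Cytosolic ribosomal proteins rose in 30 of 42 members, or 36 adjusted over the list alone, with RPL37 at 0.29 and RPS27 at 0.33, but in 12 when libraries were scaled by size alone (median 0.18, camera adjusted p = 7.21e-07, adjusted p = 0.389 with an estimated correlation).

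Lipid synthesis genes were lower. In the cholesterol biosynthesis list 21 of 25 members fell and 1 rose, 22 and 1 adjusted over the list alone (median log2 fold change -0.55, camera adjusted p = 5.21e-11, adjusted p = 0.102 with an estimated correlation). INSIG1, a sterol-regulated anchor of SREBP processing, went from 160.3 ± 6.13 to 71.8 ± 6.59 CPM (-1.16, SE 0.065, adjusted p = 7.19e-16). MSMO1, a sterol oxidase, went from 71.4 ± 5.76 to 34.5 ± 2.11 CPM (-1.05, SE 0.076, adjusted p = 5.2e-13), and DHCR7, an enzyme of the last step of cholesterol synthesis, had -0.81. Among 28 fatty acid and lipid metabolism genes 14 fell and 2 rose, 15 and 3 adjusted over the list alone (median -0.27, camera adjusted p = 8.45e-05, adjusted p = 0.255 with an estimated correlation). FASN, the fatty acid synthase, had -0.90, FADS2 -0.80 and SREBF1, a regulator of lipid synthesis, -0.71 on the log2 scale, and LPIN1 fell to 0.499 of its level.

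Genes of TGF-beta response, matrix contact and plasminogen activation were higher in part. The TGF-beta response list had 13 of 22 members higher and 2 lower, 14 and 2 adjusted over the list alone (median 0.37, camera adjusted p = 5.39e-06, adjusted p = 0.0975 with an estimated correlation). CTGF, a matricellular protein that is also a YAP target, went from 133 ± 7.97 to 503 ± 2.69 CPM (log2 fold change 1.92, SE 0.056, adjusted p = 1.86e-23), JUNB from 42.5 ± 0.97 to 142 ± 14.5 CPM (1.74, SE 0.071) and ID3 rose by 2.20. The YAP and TEAD list had 12 of 25 members higher and none lower, also adjusted over the list alone, with CYR61 at 1.42 and IGFBP3 at 1.02 (median 0.27, camera adjusted p = 0.000288, adjusted p = 0.192 with an estimated correlation). In the plasminogen activation list 9 of 18 rose and 1 fell, TFPI, also adjusted over the list alone (median 0.14, camera adjusted p = 0.00323, adjusted p = 0.235 with an estimated correlation). PLAU, which encodes urokinase, rose by 0.91, its receptor gene PLAUR by 1.36 and SERPINB8 by 1.09, while PLAT, encoding the tissue-type activator, had -0.32 (SE 0.35) and did not pass. Integrin and focal adhesion genes rose in 17 of 30 members and fell in 1, 19 and 1 adjusted over the list alone and 14 and 5 with library size alone, led by ZYX at 1.31 and RHOB at 1.17 (median 0.25, camera adjusted p = 4.21e-05, adjusted p = 0.235 with an estimated correlation).

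Mesenchymal and EMT genes rose in 14 of 26 members and fell in 2, also adjusted over the list alone, with THBS1 at 1.65 and TPM1 at 0.82 (median 0.19, camera adjusted p = 0.00384, adjusted p = 0.19 with an estimated correlation). SNAI1 and ZEB1 were among those that rose, by 0.87 and 0.42, and SPARC and WNT5A fell, at -1.51 and -0.62. VIM, CDH2 and FN1, also in the list, had log2 fold changes of 0.02, 0.08 and -0.28 and did not pass. Angiogenic and growth factor genes rose in 16 of 34 members and fell in 5, also adjusted over the list alone, with HBEGF and EREG, ligands of the EGF receptor, at 2.30 and 0.99 (median 0.19, camera adjusted p = 0.00435, adjusted p = 0.19 with an estimated correlation). Leaving out genes that stand in 2 or more lists ended the calls for this list, for plasminogen activation and for ferroptosis and glutathione (camera adjusted p = 0.392, 0.0864 and 0.253). In the extracellular matrix list 12 of 31 members rose and 4 fell, 12 and 5 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0846), though it was with limma-voom (0.0105), a mean of 10 CPM (0.0172) or the GC and length offset (0.0423), and without CAF replicate 3 (0.0386) or PAI-1 replicate 2 (0.0294). Matrix proteases and inhibitors had 8 of 22 members higher and 2 lower, 8 and 4 adjusted over the list alone and 6 and 5 with library size alone, and no call by camera (0.371). Fry called that list (adjusted p = 0.0014).

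**Figure D3:**
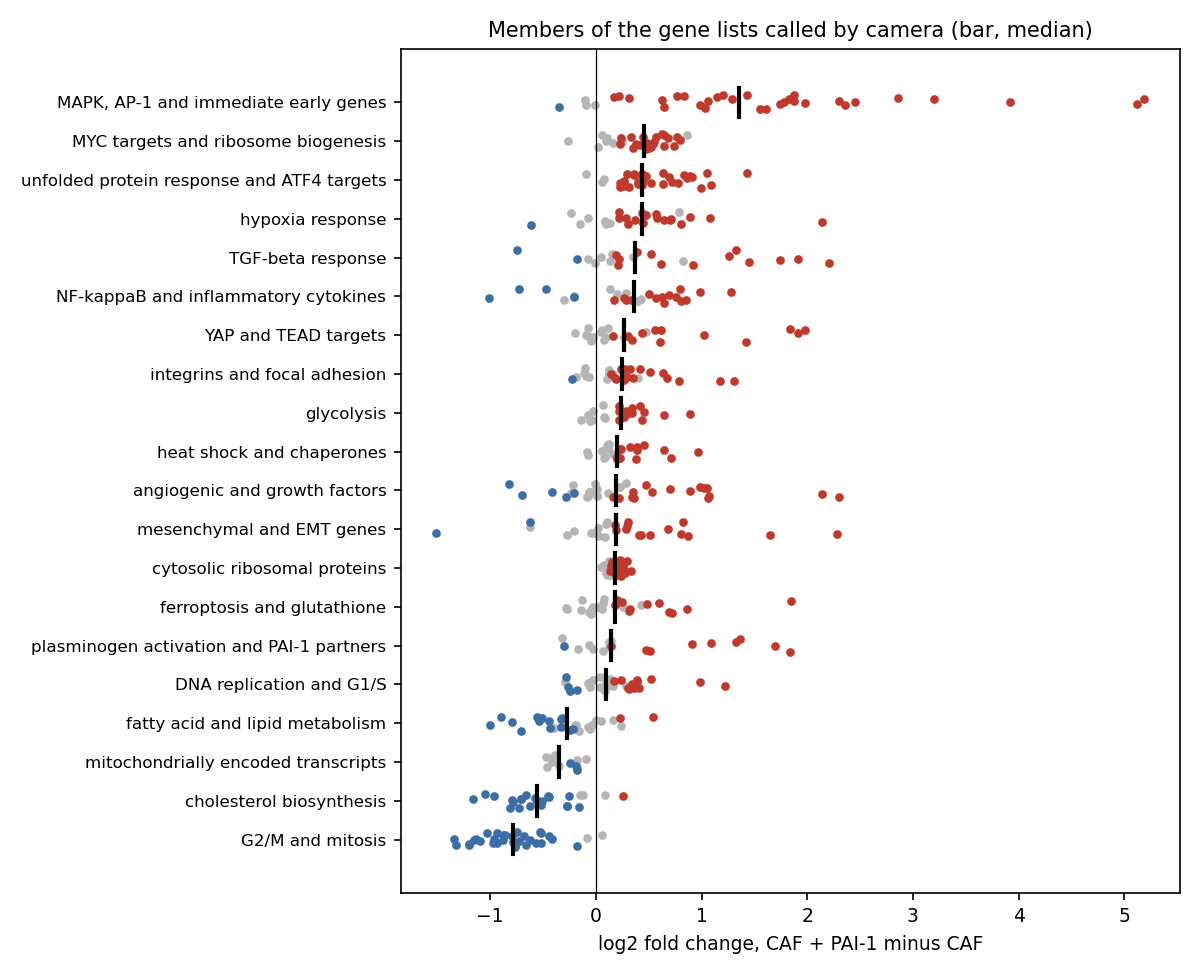
Log2 fold change (horizontal axis) of each tested member of the 20 lists that camera called (vertical axis), with red for members that rose, blue for members that fell, grey for the others and a bar at the median. Immediate early genes have the highest median, 1.36, and mitosis genes the lowest, -0.79. With library size alone the ribosomal protein members that rose number 12, not 30.

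Genes of hypoxia and glycolysis were higher, while mitochondrially encoded transcripts were lower by camera and not called by fry. Of 27 hypoxia response genes 17 rose and 1 fell, HILPDA, 18 and 2 adjusted over the list alone (median 0.43, camera adjusted p = 6.88e-06, adjusted p = 0.255 with an estimated correlation). ANGPTL4, a secreted regulator of lipoprotein lipase, went from 83.6 ± 4.23 to 368 ± 33.3 CPM (log2 fold change 2.14, SE 0.064, adjusted p = 7.89e-23) and VEGFA from 94.0 ± 5.07 to 153 ± 1.54 CPM (0.70, SE 0.059, adjusted p = 1.56e-11). Glycolysis genes rose in 15 of 23 members and fell in none, also adjusted over the list alone, with PFKFB3 at 0.89 and GPI at 0.45 (median 0.23, camera adjusted p = 0.000202, adjusted p = 0.308 with an estimated correlation). Of the 13 mitochondrially encoded transcripts 3 fell and none rose, also adjusted over the list alone, and MT-CO2 had -0.24 (median -0.35, camera adjusted p = 0.00628, adjusted p = 0.499 with an estimated correlation, fry adjusted p = 0.132). PAI-1 replicate 2 stood apart here, with 3.78% of its counts from mitochondrial genes. The other PAI-1 libraries had 5.12% and 4.76% and the CAF libraries 5.53% to 5.92%. It also stood apart over all genes. Its chi-square per degree of freedom was 9.51 and 6.63 against PAI-1 replicates 1 and 3, which had 3.39 between them. On the second principal component it lay at -23.9, and they lay at 18.9 and 6.31. Without PAI-1 replicate 2, 8 of 13 transcripts fell, with a median of -0.17 (camera adjusted p = 0.013), and 4673 genes changed in all. Nuclear genes of oxidative phosphorylation had 2 of 37 members lower and none higher, 0 and 0 adjusted over the list alone and 9 lower and none higher with library size alone, and no call (camera adjusted p = 0.778).

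Ferroptosis and glutathione genes rose in 11 of 25 members and fell in none, 12 and 2 adjusted over the list alone and 8 and 3 with library size alone (median 0.18, camera adjusted p = 0.00556, adjusted p = 0.18 with an estimated correlation). HMOX1, the haem-degrading oxygenase, rose by 1.85 and SLC3A2 and SLC7A11, the subunits of the cystine importer, by 0.72 and 0.69. The NRF2 target list had 7 members higher and 6 lower of 21, 8 and 8 adjusted over the list alone, with HMOX1 and SRXN1 higher at 1.85 and 1.13, and no call (camera adjusted p = 0.663). Its median was -0.03 and its mean 0.15, so that they differ in sign, as do the median and mean for epithelial genes (0.01 and -0.04), fibroblast markers (0.10 and -0.07), apoptosis regulators (0.06 and -0.0025) and autophagy genes (0.0022 and -0.0079).

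Inflammatory and immune lists were mixed. NF-kappaB and cytokine genes rose in 15 of 26 members and fell in 4, 16 and 4 adjusted over the list alone, with NFKBIA, the pathway's inhibitor, at 0.98 and BIRC3 at 0.80 (median 0.36, camera adjusted p = 0.000279, adjusted p = 0.255 with an estimated correlation). In the interferon response list 6 of 30 members fell, with STAT2 at -0.44, and 2 rose, IRF1 at 0.64 and ISG20 at 0.55, also adjusted over the list alone (camera adjusted p = 0.0915, or 0.0372 without CAF replicate 1 and 0.0274 with a mean of 10 CPM). JAK-STAT3 response genes had 9 higher and 4 lower of 21, also adjusted over the list alone (camera adjusted p = 0.115, or 0.0291 with limma-voom), with MCL1, an anti-apoptotic gene, at 1.31 and the cytokine gene LIF at 1.30. Antigen presentation and checkpoint genes had 6 higher and none lower of 22, also adjusted over the list alone (0.143), with NT5E at 0.56.

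Cell death, damage and developmental lists held members that went both ways and were not called by camera. Fry called apoptosis regulators (adjusted p = 0.00038) and p53 targets (0.000635). Apoptosis regulators had 13 higher and 8 lower of 32, 14 and 9 adjusted over the list alone, with MCL1 higher and BMF lower (camera adjusted p = 0.415). The p53 target list had 8 higher and 5 lower of 24, 10 and 8 adjusted over the list alone (0.371). GADD45A rose by 1.54 and CDKN1A, the p21 cell cycle inhibitor, by 1.13, while TP53INP1 had -1.78, CCNG1 -0.83 and MDM2 -0.50. WNT and NOTCH response genes had 6 higher and 6 lower of 21, also adjusted over the list alone (0.637), with JAG1 at 0.67 and HES1 at 1.13, while AXIN2, a WNT target, had -1.65. Autophagy and lysosome genes had 8 higher and 9 lower of 36, 8 and 12 adjusted over the list alone (0.86).

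The sources used here do not say whether CAF RNA could enter the libraries. Marker genes of other cell types were mostly at the level of a few counts. Of 32 fibroblast markers, 18 were under 1 CPM in every library, and DCN, LUM, COL1A2, PDGFRA, PDGFRB, FAP and POSTN together had 13 counts in the CAF libraries and 9 in the PAI-1 libraries. The most abundant fibroblast list members, S100A4 and COL1A1, went from 192 ± 11.7 to 310.1 ± 35.8 CPM and from 186 ± 19.9 to 257 ± 16.5 CPM, and both rose (log2 fold changes 0.69 and 0.47, adjusted p = 4.91e-09 and 1.71e-06). In the 14 members tested, 2 rose and 3 fell, also adjusted over the list alone, SPARC among them at -1.51 (camera adjusted p = 0.92). Of 21 leukocyte markers 19 were under 1 CPM in every library, and the highest, CD14 and ITGAM, had 5.52 ± 0.55 and 2.40 ± 0.60 CPM in the CAF group, with log2 fold changes of 0.12 and 0.42 that did not pass. Of 13 endothelial markers 10 were under 1 CPM and 2 of the 3 tested rose, ESAM and KDR. ENG had 42.8 ± 1.58 CPM and a log2 fold change of 0.01 that did not pass, KDR, with 8 to 36 counts in a library, rose by 1.13 (adjusted p = 0.0172), and ESAM rose 1.37-fold from 8.81 ± 0.66 CPM (log2 fold change 0.45, adjusted p = 0.00874), a call lost without PAI-1 replicate 1 (log2 fold change 0.35, adjusted p = 0.0741).

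Levels of lineage genes are given because the extraction text names Cal27, a line of squamous carcinoma. Of 26 squamous keratinocyte genes 23 were under 1 CPM in every library, with 1 count each of KRT5 and KRT14 over all libraries, while KRT15 had 11.5 ± 1.67 CPM in the CAF group and a log2 fold change of 0.04 that did not pass, and S100A2 rose by 1.09. Of 25 pancreatic ductal and tumour lineage genes 7 were under 1 CPM. KRT19, a ductal keratin, rose from 208 ± 7.83 to 268 ± 25.7 CPM (0.37, adjusted p = 1.25e-05), and AGR2 had 197 ± 9.23 and 188 ± 12.4 CPM (-0.07, adjusted p = 0.421). CDKN2A had 0 counts in all libraries, which allows a level of up to 0.187 to 0.22 CPM, depending on the library. The pancreatic list had 4 higher and 4 lower of 17, 4 and 5 adjusted over the list alone (camera adjusted p = 0.86), and epithelial genes 8 higher and 6 lower of 24, 8 and 7 adjusted over the list alone and 4 and 7 with library size alone (0.894), with CLDN1 at 0.99 and ELF3 at -1.45. With library size alone in place of TMM, the medians of the epithelial, pancreatic, apoptosis, p53, JAK-STAT3, WNT and NOTCH, antigen presentation, protease and autophagy lists turned from above to below 0, that of autophagy also with RLE. With library size alone the members higher and lower numbered 8 and 6 for extracellular matrix, 8 and 3 for plasminogen activation and 9 and 5 for DNA replication. They were 2 and 9 for interferon response, 9 and 7 for JAK-STAT3, 10 and 9 for apoptosis, 8 and 8 for p53 and 6 and 8 for NRF2. They numbered 6 and 13 for autophagy and 0 and 5 for mitochondrially encoded transcripts. In all, camera called 20 of 35 lists, 16 higher and 4 lower, while fry called 27. Camera asks whether a list changed more than other genes, and fry whether its members changed at all. The lists called by fry leave out the mitochondrially encoded transcripts. They take in the extracellular matrix, interferon, JAK-STAT3, antigen presentation, protease, apoptosis, p53 and NRF2 lists, which camera did not call. For the apoptosis and NRF2 lists the median and mean differ in sign, so the call gives no clear direction.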

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

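The offset for GC content and transcript length and the fit without mitochondrial genes were chosen after seeing the data. The number of changed genes lay between 3913 (DESeq2) and 5098 (GC and length offset) in every alternative except glmTreat against a 1.2-fold change, which by its construction asks for larger effects and gave 1611 genes, 828 higher and 783 lower. No gene was called in the opposite direction in any of 18 alternatives. Leaving out a library in turn gave 3942 to 4673 changed genes. The replicate numbers did not pair the libraries: same-numbered deviations from group means correlated at 0.0023, 0.012 and 0.0063, and the replicate block gave 5069 genes, 2708 higher and 2361 lower. Camera called 17 to 22 lists in the other settings it was run in and fry called 27, but camera called 1 with an estimated correlation. A higher correlation among a list's own members does not account for all lost calls. The TGF-beta and ferroptosis lists lost theirs (camera adjusted p = 0.0975 and 0.18) at estimated correlations of -0.013 and 0.0014, under the preset 0.01. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries and not from the number of genes, which lowers its power. A lost call is therefore not by itself a sign of correlated members. How much each part contributed was not tested. Genes and lists that missed the threshold both ways changed direction, of the median or of the list test, under some settings. With library size alone the median log2 fold change of all tested genes was -0.068, against -0.0015 with TMM. Values near 0 turned below it with this shared shift. For the other settings the cause was not tested. ENG had -0.059 with library size alone, -0.014 with a mean of 10 CPM, -0.029 with the GC and length offset and -0.034 to 0.043 with a library left out, and KRT15 had -0.023 with library size alone and -0.027 to 0.17 with a library left out. With no filter the list medians were 0.012 for autophagy, -0.051 for fibroblast markers, 0.055 for NRF2 targets and -0.017 for oxidative phosphorylation. With a library left out they were -0.018 to 0.0024 for autophagy, 0.045 to 0.14 for fibroblast markers, -0.061 to 0.0063 for oxidative phosphorylation, -0.11 to 0.097 for histones, -0.034 to 0.092 for epithelial genes and -0.076 to 0.049 for pancreatic genes, and they came to -0.028 for p53 targets without CAF replicate 2 and to -0.0017 for WNT and NOTCH without PAI-1 replicate 3. For fibroblast markers it was the direction of the list test that changed there and with the GC and length offset. Without genes shared between lists they were -0.10 for epithelial genes, -0.14 for NRF2 targets, -0.065 for pancreatic genes, -0.020 for matrix proteases and -0.0010 for autophagy. Pancreatic genes had -0.094 with a mean of 10 CPM, -0.072 with 1 CPM in 3 libraries and -0.0094 with the GC and length offset, autophagy -0.021 and -0.0040 with these filters, epithelial genes -0.026 with the offset, histones 0.078 with 1 CPM in 3 libraries and -0.012 with limma-voom, and fibroblast markers 0.063 with the GC and length offset. RPL37, RPS27, KRT19 and ESAM were not called by glmTreat. The lists were not run with DESeq2, glmTreat or without robust estimation, which do not enter camera, and the pseudocount alternative does not apply to counts. Depth limits genes near 3 counts, such as EGR2 in the CAF libraries.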

Other observations

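The gene families and tests in this part were chosen after seeing the data, except the count of other splits. Camera called 21 of 33 families, and none with an estimated correlation. Among them HOX genes and their antisense RNAs, which set body position in development, were lower: 18 of 27 fell and 1 rose, HOXB9, with a median log2 fold change of -0.57 (camera adjusted p = 2.6e-07 over the families, adjusted p = 0.0833 with an estimated correlation). HOXC13 had -0.86 (SE 0.068), HOXC6 -1.03 (SE 0.095) and HOXB3 -0.98 (SE 0.096). These genes lie close together and partly overlap their antisense RNAs, so reads of neighbours cannot be told from each other where strand was not used in counting. Host genes of small nucleolar RNAs named SNHG rose in 12 of 18 members and fell in none, with SNHG15 at 0.92 and SNHG8 at 0.94 (median 0.34, camera adjusted p = 0.000581, adjusted p = 0.0833 with an estimated correlation). Cytosolic tRNA synthetases, many of them ATF4 targets, rose in 12 of 17 members and fell in none, with GARS at 0.79 and SARS at 0.61 (median 0.35, camera adjusted p = 4.82e-06, adjusted p = 0.0833 with an estimated correlation). With library size alone these counts were 0 higher and 19 lower for HOX genes, 10 and 0 for SNHG genes and 11 and 1 for tRNA synthetases.

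The real split of the 6 libraries gave 4810 changed genes, and the highest of the other splits gave 1. Each of the other splits mixes both arms in its groups. A difference between the arms, of whatever cause, then widens the spread within groups and lowers the count. Since 3 libraries against 3 make 10 splits, and 1 of them, the real one, gave as many, a share under 0.05 cannot be reached.

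Immediate early genes were the group with the largest rise, and 3 explanations were weighed. A bias of GC content or transcript length is argued against, since the median log2 fold change was 1.36 before and 1.36 after an offset for both, with a 95% interval from 1.03 to 1.83 over resampled members. A candidate explanation is a stimulus of the growth factor or serum type, which would lower FOXO pathway genes and raise SRF and actin targets. FOXO genes had a median of -0.42, with 11 of 16 lower and 1 higher, and SRF targets 0.40, with 15 of 18 higher and 1 lower (camera adjusted p = 0.000195 and 1.12e-06, both adjusted p = 0.0833 with an estimated correlation). Without the genes that also stand in the fixed lists, GABARAPL1, BCL6 and SESN1 for FOXO and FLNA and VCL for SRF, the medians were -0.43 and 0.37 (camera adjusted p = 0.00149 and 7.86e-06, both adjusted p = 0.0972 with an estimated correlation). Both families were chosen after the changes were seen, so these values describe them and do not test the explanation. They also do not say when during the 72 h a stimulus acted. Such a stimulus, if there was one, may have come from PAI-1 itself or from another difference between the CAF of the arms. It may also have come from a difference in handling or medium, and these cannot be told apart. Every library of an arm shares its treatment and, beyond the 72 h of co-culture, details of handling at harvest are not given in the sources used here. The list's mean log2 CPM differed by 1.4985 between arms and had an SD of at most 0.016 within one, which excludes none of these sources.

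Mitosis genes were lower as a group. A bias of GC content or length is argued against by a median of -0.79 after the offset (95% interval -0.94 to -0.69). The levels of the 7 fibroblast genes counted above argue against dilution by RNA of fibroblasts, assuming that CAF express them. A fall of this size needs 42.1% of the RNA from other cells, and the 7 genes reached 0.199 CPM together in the PAI-1 libraries (upper exact 95% limit 0.379, without TMM scaling). The 7 genes were chosen after seeing the data, so this is not an independent test. Other members of the fibroblast list were abundant in both groups, such as FBLN1 with 118 CPM in the CAF and 107 CPM in the PAI-1 libraries, without TMM scaling. Which cells made those RNAs was not tested. A first test of dilution, the distance of the epithelial median from the mitosis median, gave 0.80, but the 95% limits of the medians came as close as 0.47, under the bound of 0.5 set for it, and it was set aside for the fibroblast genes after that result. Slower cycling, or an effect of PAI-1 on it, stays open, and no test of cell number was used here.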
